A study of Venturia canescens with 18 samples.

How the data were processed

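RNA was sequenced from heads of female Venturia canescens, a parasitoid wasp reared on larvae of the flour moth Ephestia kuehniella. Newly emerged virgin females were boxed singly for at most 10 min with an unrelated male (a compatible mate), with a brother (an incompatible mate) or with no male (the isolated control), per the labels' protocols. Heads were pooled before extraction, and the protocols give 10 heads per condition. They do not say whether that number is per biological replicate, or whether the replicates came from separate families or days, so p-values measure only the spread between these pools. Polyadenylated RNA was made into stranded TruSeq libraries and read as 125 bp pairs on an Illumina HiSeq instrument, per the labels' protocols. The labels give 3 groups, 3 biological replicates per group and 2 technical replicates of each, or 18 libraries. The library titles carry different run and lane names for the first and second technical replicates.

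The authors deposited one table of raw counts, with 1 column per library and 16752 loci named by XLOC identifiers of the kind that Cufflinks writes. Trimmomatic 0.36, TopHat, Cufflinks and HTSeq are named in the submitters' processing notes, without a role or an order, and the genome build and annotation are not given in the sources used here. The deposited counts are whole numbers, are not normalised and have no rows for unassigned reads. All 18 columns were matched to samples by the condition, the replicate number and the letter that marks the second technical replicate. The column names that mention neither kin nor non-kin were taken as the isolated group, the one condition without a male. None of the XLOC identifiers occurs in the RefSeq gene table of the species that was searched, and the file pairs them with no gene names or coordinates. Loci are therefore reported by identifier, and the gene lists fixed beforehand, which need names, were not tested. How the counting treated strand, overlapping loci or near-identical copies is not given in the sources used here, so reads shared between such loci cannot be told apart.

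Counts of the 2 technical replicates were summed, which gave 9 pools of 62341897 to 103527471 counts from libraries of 22079293 to 67940613. A floor of 3 counts corresponded to between 0.029 and 0.0481 CPM (counts scaled to library size) per pool. Floors and counting intervals cover counting error only, because PCR reads without molecular identifiers are not independent molecules. In the file 540 loci had no counts in any library. The technical replicates of a pool had Spearman correlations of log2 CPM between 0.9886 and 0.9933. Their mean index of dispersion over loci with at least 10 counts was 8.46 to 17.5, where counting noise alone gives a mean of 1. The median was 1.7 to 2.1, where counting noise alone gives a median under 1. Technical replicates thus differed by more than counting noise but by less than pools did. The common biological coefficient of variation was 7.15% between technical replicates and 26.3% between pools of a group.

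The main test was the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3 on the summed counts of all 9 pools in one fit with a coefficient per group. The filter filterByExpr kept 15486 loci, library sizes were scaled by TMM, and p-values were adjusted by the Benjamini-Hochberg method over all loci tested, with a threshold of 0.05. Contrasts were brother minus isolated, unrelated minus isolated, brother minus unrelated, and the mean of both courted groups minus isolated, and a joint F-test asked for any difference among the 3 groups. Standard errors of log2 fold changes were taken as the absolute log2 fold change divided by the square root of F. CPM values use TMM-scaled library sizes. For a locus with few counts in one group, the ratio of summed counts was given with an exact 95% interval from the conditional binomial distribution. Where a locus had no counts in the brother pools, its fold was taken at the bound given by 3 counts over those pools. The loci named were those past the threshold whose pools did not overlap between the groups compared, ordered by adjusted p and then by the size of the change, with at most 2 higher and 2 lower per comparison. The test, the contrasts, the naming rule and most of the alternatives were fixed before the data were examined.

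The fit was tested on simulated counts with the means, library sizes and spread of the real loci, 100 loci changed 2-fold and 100 changed 4-fold. Each simulated locus had the same spread in every pool and varied independently of the others. In the real data the spread was larger with brother pool 1 than without it, so the shares below describe pools of even spread. With the spread of all 9 pools, 50% of the 2-fold and 69% of the 4-fold changes were recovered for brother against isolated, 51% and 74% for unrelated against isolated, and 48% and 77% for brother against unrelated. With the spread estimated without brother pool 1, the corresponding shares were 74% and 87%, 74% and 88%, and 76% and 91%. Between 7 and 15 of the 15286 unchanged loci were called.

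The alternatives fixed beforehand were DESeq2 1.42.0 with its independent filtering and, for the joint test, its likelihood-ratio test, RLE and upper-quartile scaling, no filter, a filter of at least 1 CPM in 3 pools, the replicate number as a block, either technical replicate alone, limma 3.58.1 voom on the 18 libraries with duplicateCorrelation, the 18 libraries as independent samples (both with the technical replicate as a covariate), a fit of only the groups compared, a robust fit, a minimum change of 2-fold, and each pool left out. Added after seeing the data were scaling by library size only, limma-voom with sample quality weights, fits without both brother pool 1 and unrelated pool 1, and the correlation of the courtship effects without brother pool 1 or with no isolated pool shared. The 2 courtship effects share the isolated pools, so their correlation was set beside 100 simulated data sets with no effect. Plots were drawn with matplotlib 3.10.9.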

Results

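The transcriptome of female wasp heads was compared after at most 10 min of courtship by an unrelated male, courtship by a brother, or isolation. Each group held 3 pools of heads, each sequenced as 2 technical replicates that were summed. The pools held 62341897, 84765233 and 74122308 counts in the isolated group, 73839115, 68684141 and 68571374 in the brother group, and 65809907, 77756638 and 103527471 in the unrelated group. The most abundant locus, XLOC_007188, took 3.22% to 5.07% of the counts in each of the 18 libraries.

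Brother pool 1 stood apart from every other pool. It scored 100.3 on the first principal component of log2 CPM, which held 40.4% of the variance, while the other 8 pools scored between -33.99 and 13.29. The second component, with 24.2% of the variance, placed brother pools 2 and 3 at -56.39 and -49.14, unrelated pools between -1.201 and 20.2, and isolated pools between 19.39 and 26.59. In brother pool 1, 1118 of 15486 loci lay over 2-fold above all other pools and 169 lay over 2-fold below all of them. In the other pools, between 0 and 37 loci lay above and between 12 and 146 below. The common biological coefficient of variation between pools of a group was 26.3%, and it was 13.7% without brother pool 1.

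**Figure D1:**
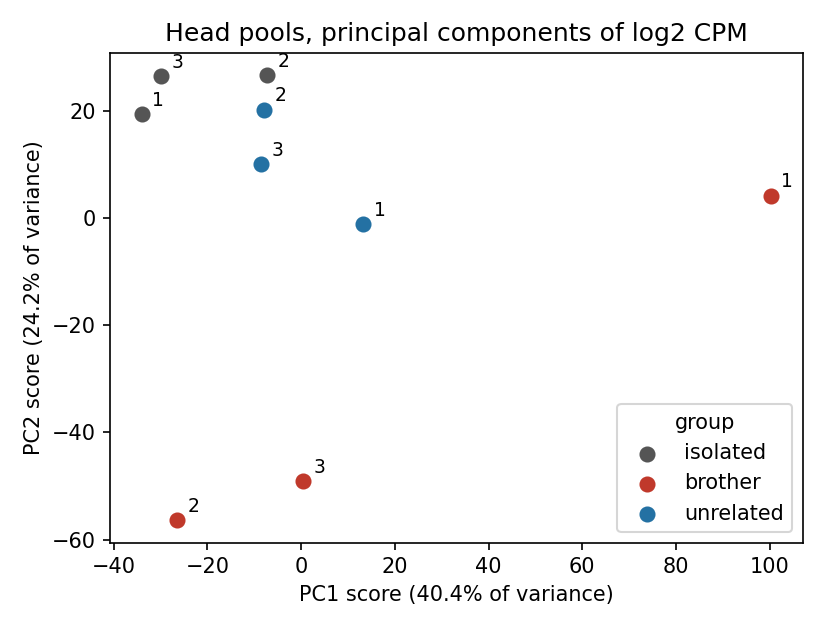
Scores of the 9 head pools on the first 2 principal components of log2 CPM (axes in score units, with the share of variance; each point is 1 pool, labelled by its replicate number and coloured by group). Brother pool 1 lies at 100.3 on the first component, and the 2 other brother pools lie lowest on the second, at -56.39 and -49.14.

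The comparison of brother-courted with isolated females asked what courtship by an incompatible male changes in the head. At an adjusted p under 0.05 (edgeR quasi-likelihood test), 82 loci were higher and 255 were lower after courtship by a brother. The higher loci rose modestly. Of the 82, 72 rose by less than 2-fold and 10 by 2- to 8-fold, with a median log2 fold change of 0.518. XLOC_006735 rose from 7.55 ± 0.556 CPM in isolated pools to 16.9 ± 0.565 CPM in brother pools (SD, n = 3 each), with a log2 fold change of 1.16 ± 0.11 (SE; edgeR adjusted p = 0.00587). XLOC_005778 rose from 13.9 ± 0.596 to 29.6 ± 2.86 CPM, with a log2 fold change of 1.09 ± 0.11 and an edgeR adjusted p of 0.00987. Both lay in between in the unrelated pools, at 11.6 ± 1.16 CPM for XLOC_006735 and 19.7 ± 2.53 CPM for XLOC_005778. The call of XLOC_005778 was lost without isolated pool 1 (edgeR adjusted p = 0.0645) and without isolated pool 3 (edgeR adjusted p = 0.0601).

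The 255 lower loci spanned a wide range of sizes. For 155 the level was lower by under 2-fold, for 31 by 2- to 8-fold, and for 69 by over 8-fold. The pools held different females, so courtship cannot be told apart here from a difference between the females used. With the 12 of the 69 that had no counts in the brother pools taken at their bound, 68 were over 8-fold lower and the median was 32.9-fold. The abundant locus XLOC_010657 stood at 162 ± 15.2 CPM in isolated pools and at 0.12 ± 0.0556 CPM in brother pools (SD, n = 3 each; edgeR adjusted p = 0.000123). Its summed counts were 35735 in the isolated and 25 in the brother pools, a 1360-fold lower level (exact 95% interval 924 to 2110, counting error only). XLOC_005068 had 1996 counts over the isolated pools and 1 count over the brother pools, a ratio of 1900 with an exact interval of 341 to 75300 (edgeR adjusted p = 0.00395), and its call was lost without brother pool 3 (edgeR adjusted p = 0.0581). Of the 69 loci that were lower by over 8-fold, 41 did not pass the test against the unrelated pools. With loci that had no counts in the brother pools taken at their bound, all 41 were over 2-fold lower by summed counts than in unrelated pools, with a median of 21-fold.

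The number of loci called for brother against isolated rested on single pools. Without brother pool 1 it was 2494 (1127 higher, 1367 lower), including all 337 of the loci above, and without brother pool 2 it was 1113. It fell to 3 without brother pool 3, to 6 without isolated pool 1 and to 6 without isolated pool 3, and it was 167 without isolated pool 2. It was also lower without an unrelated pool, at 183, 69 and 41 for pools 1, 2 and 3, and was 61 (3 higher, 58 lower) when the 6 brother and isolated pools were fitted alone. With library sizes unscaled the split was 46 higher and 357 lower, and with DESeq2 it was 891 higher and 848 lower.

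**Figure D2:**
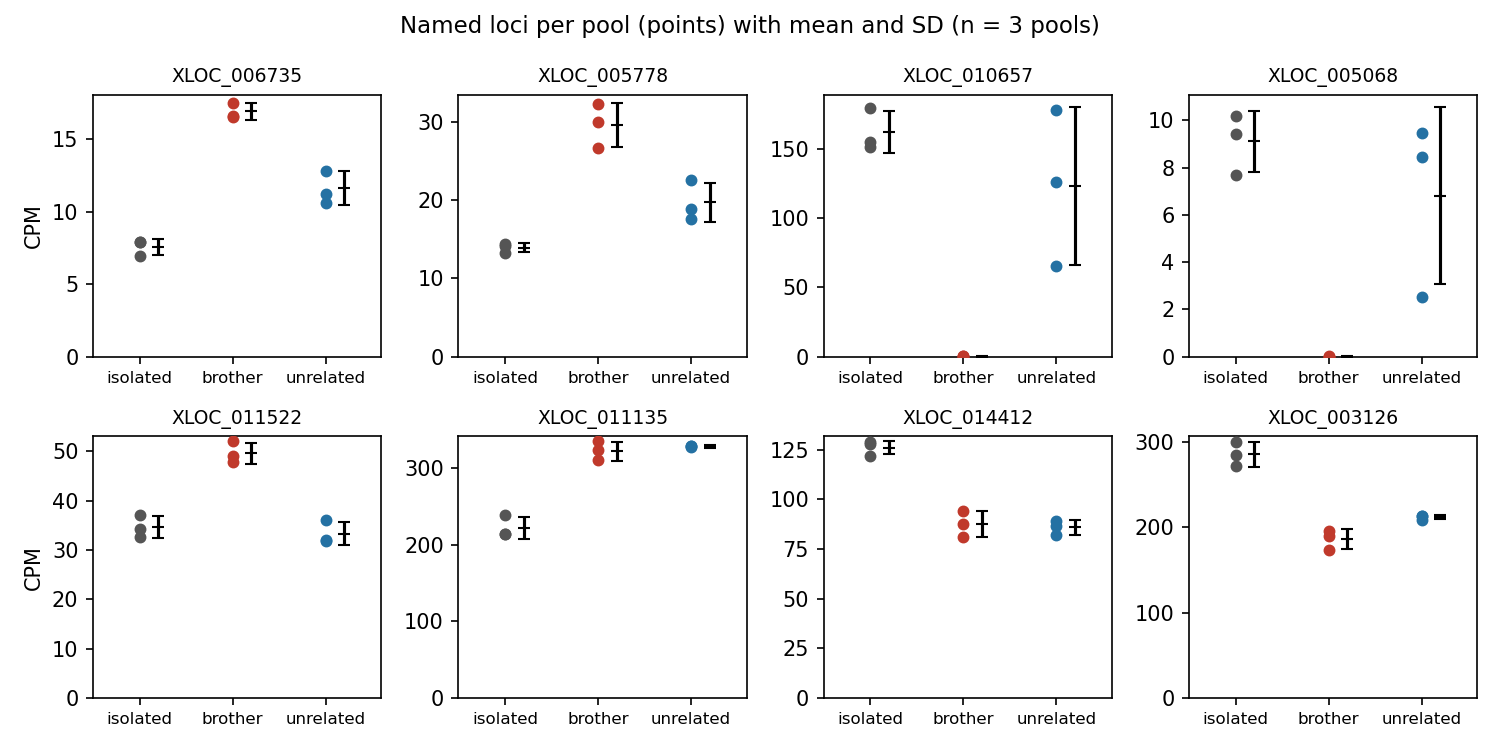
CPM of the 8 named loci in each pool (points, vertical axis in CPM starting at 0) with the mean and SD of the 3 pools of each group (bars). XLOC_010657 and XLOC_005068 are near 0 in the brother pools alone, at 0.12 and 0.0051 CPM on average, while XLOC_011135 is at 322 and 328 CPM in the 2 courted groups and at 222 CPM in isolated pools.

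**Figure D3:**
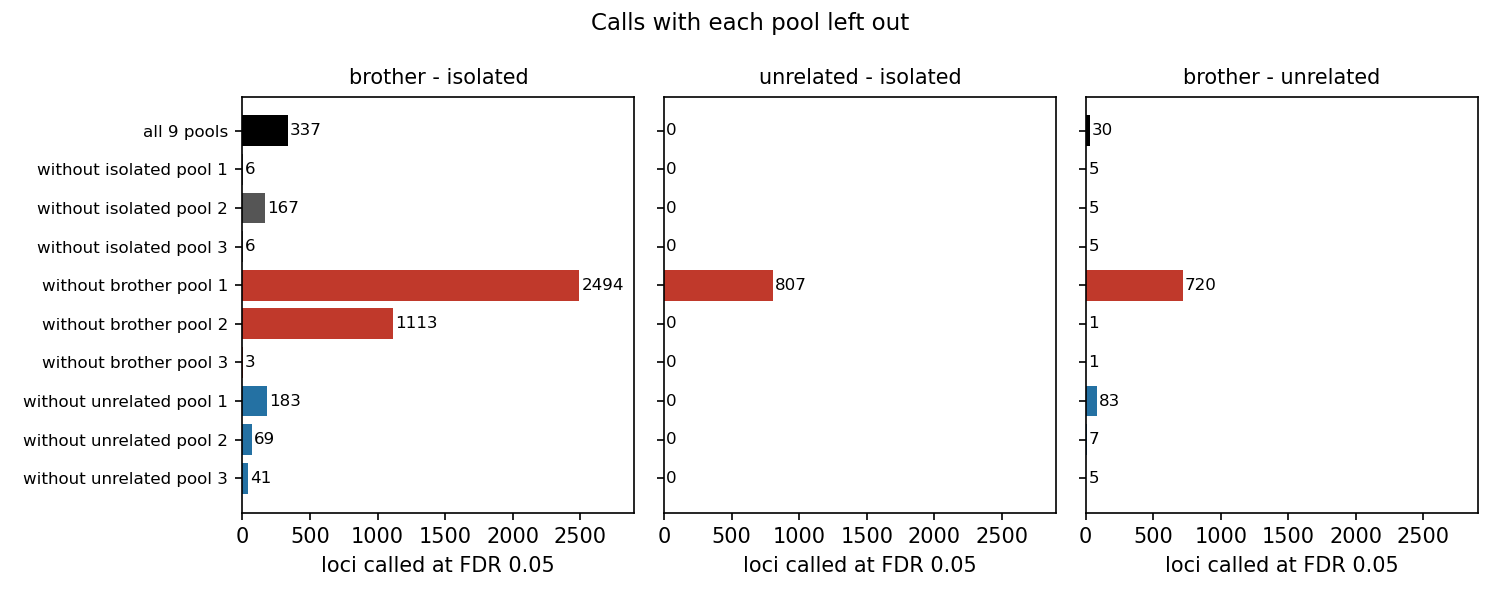
Number of loci called at an adjusted p under 0.05 (horizontal axis) with all 9 pools (black) and with each pool left out in turn (bars coloured by the group of the pool left out), for 3 comparisons. Among these fits, unrelated against isolated has calls only without brother pool 1, where there are 807.

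Courtship by an unrelated male, against isolation, asked for the response to a compatible mate. In the fit of all 9 pools no locus passed the threshold. The smallest edgeR adjusted p was 0.13, and 1678 of 15486 loci had an unadjusted p under 0.05. That fit shares its estimate of spread with brother pool 1. When the 6 unrelated and isolated pools were fitted alone, 543 loci were higher and 504 lower after courtship. Of the higher loci, 452 rose by less than 2-fold, and of the lower loci, 456 fell by less than 2-fold. XLOC_011135 was at 222 ± 14.1 CPM in isolated and 328 ± 1.37 CPM in unrelated pools (SD, n = 3 each), a log2 difference of 0.56 ± 0.062 (SE) with an edgeR adjusted p of 0.13 over all 9 pools and 0.0096 in the fit of the 6 pools. XLOC_014412 was at 126 ± 3.32 CPM in isolated and 85.8 ± 3.64 CPM in unrelated pools, with edgeR adjusted p of 0.133 and 0.0096 in the same fits. These loci were named by the comparison of both courted groups with isolation. Without brother pool 1, 438 loci were higher and 369 lower. DESeq2 called 424 loci, among the 9292 to which it gave an adjusted p. limma-voom called 390 with duplicateCorrelation on the 18 libraries and 2316 with quality weights on the 9 pools, the last chosen after seeing the data. Leaving out any one of the other 8 pools from the fit of all 9 left the count at 0.

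Courtship by a brother was then compared directly with courtship by an unrelated male, the contrast in which both groups met a male. A single locus was higher and 29 were lower after courtship by a brother (edgeR, adjusted p under 0.05). The higher locus, XLOC_011522, was at 49.6 ± 2.15 CPM in brother, 33.3 ± 2.36 CPM in unrelated and 34.6 ± 2.22 CPM in isolated pools (SD, n = 3 each), a log2 fold change of 0.57 ± 0.078 (SE; edgeR adjusted p = 0.0304) between the courted groups. Its call was lost without isolated pool 1, 2 or 3, brother pool 2 or 3, or unrelated pool 2 or 3, with edgeR adjusted p from 0.0745 to 0.177 and log2 fold changes from 0.54 to 0.60. It was also lost with library sizes unscaled (edgeR adjusted p = 0.0523) and when the 2 groups were fitted alone (edgeR adjusted p = 0.239). With the replicate number as a block it was lost too (edgeR adjusted p = 0.0831). Of the 29 lower loci, 28 differed by over 8-fold, also with loci of no counts in the brother pools taken at their bound. XLOC_010657 was 1090-fold lower by summed counts in brother than in unrelated pools (exact 95% interval 740 to 1690), and XLOC_005068 was 1550-fold lower on 1 count (exact interval 278 to 61400). The call of XLOC_005068 was lost without brother pool 2 (edgeR adjusted p = 0.0659), without brother pool 3 (edgeR adjusted p = 0.106) and when the 2 groups were fitted alone (edgeR adjusted p = 0.17). All 29 were also called lower in brother than in isolated pools. In the brother pools 13 of the 29 had at most 3 counts over the 3 pools.

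The 29 loci together made up 311, 311 and 351 CPM in isolated pools 1 to 3, and 4.31, 2.01 and 3.46 CPM in brother pools 1 to 3. In unrelated pools 1 to 3 they made up 113, 412 and 293 CPM. Unrelated pool 1 was thus low for the set, at a median of 28.6% of the level of unrelated pools 2 and 3. The 29 loci were chosen from these same pools for being lower in brother than in unrelated pools. All 29 stayed lower by over 2-fold in that comparison whichever pool was left out, which is no independent support. Their number past the threshold depended on the pools in the fit. All 29 passed without brother pool 1 or without unrelated pool 1, 7 without unrelated pool 2, 5 without unrelated pool 3 or without any one isolated pool, and 1 without brother pool 2 or 3. Over all loci, the comparison called 720 without brother pool 1 (386 higher, 334 lower) and 83 without unrelated pool 1. It called 5 without any one isolated pool, 7 without unrelated pool 2, 5 without unrelated pool 3 and 1 without brother pool 2 or 3. When the 6 brother and unrelated pools were fitted alone it called 1 locus, XLOC_010657, which was lower (edgeR adjusted p = 0.0139). DESeq2 called 57 higher and 134 lower.

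**Figure D4:**
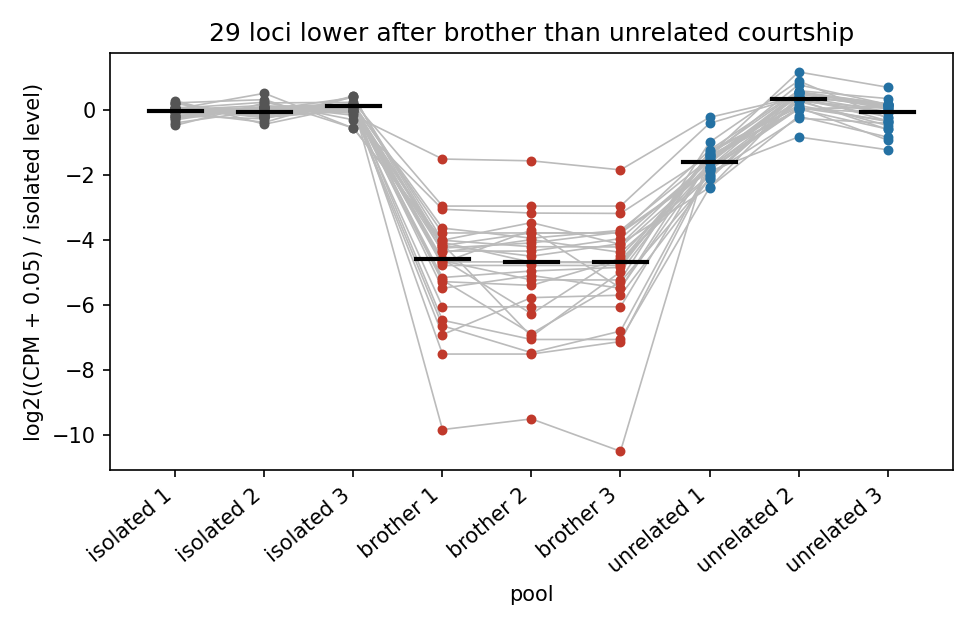
The 29 loci lower in brother than in unrelated pools, as log2 of CPM + 0.05 relative to the mean of the isolated pools (vertical axis) in each of the 9 pools (horizontal axis). Grey lines join the values of a locus and black bars are medians; unrelated pool 1 lies between the brother pools and the remaining pools, at a median of 28.6% of unrelated pools 2 and 3.

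The mean of both courted groups was compared with isolation, a contrast that a change in either courted group can carry. It called 40 loci higher and 130 lower (edgeR, adjusted p under 0.05). In unrelated against isolated pools, all 40 higher loci and 99 of the 130 lower loci had the same sign at an unadjusted p under 0.05 (edgeR), shares that are raised by selection because the contrast includes those pools. Of the 130, 26 were also called between brother and unrelated pools, among them 19 of the 23 that were lower by over 8-fold. For these 23 the median log2 difference of unrelated from isolated pools was -0.35. XLOC_010657, at a log2 fold change of -5.38 ± 0.31 (SE; edgeR adjusted p = 0.000561) in this contrast, differed by -0.39 ± 0.3 between unrelated and isolated pools (edgeR adjusted p = 0.675). XLOC_011135 rose by 0.55 ± 0.055 on the log2 scale (SE; edgeR adjusted p = 0.0152), from 222 ± 14.1 CPM in isolated pools to 322 ± 12.3 CPM in brother and 328 ± 1.37 CPM in unrelated pools. XLOC_006735 rose by 0.89 ± 0.094 on the same scale with the same adjusted p from edgeR. XLOC_014412 fell from 126 ± 3.32 CPM to 87.5 ± 6.4 CPM in brother and 85.8 ± 3.64 CPM in unrelated pools, a log2 fold change of -0.54 ± 0.057 (edgeR adjusted p = 0.0152). XLOC_003126 fell from 285 ± 14.6 CPM to 186 ± 11.6 and 212 ± 2.71 CPM in brother and unrelated pools, a log2 fold change of -0.52 ± 0.055 (edgeR adjusted p = 0.0152). Brother minus unrelated pools, XLOC_011135 and XLOC_014412 differed by -0.02 ± 0.062 and 0.03 ± 0.067 on the log2 scale (SE), within the spread between pools. By the same measure XLOC_006735 differed by 0.55 ± 0.1 (edgeR adjusted p = 0.119, and 0.0267 without brother pool 1) and XLOC_003126 by -0.18 ± 0.065 (edgeR adjusted p = 0.627). XLOC_011135, XLOC_006735, XLOC_014412 and XLOC_003126 kept their direction but lost their call without isolated pool 1 (edgeR adjusted p = 0.142), isolated pool 3 (edgeR adjusted p from 0.101 to 0.105), brother pool 3 (edgeR adjusted p = 0.0562) or unrelated pool 3 (edgeR adjusted p = 0.0752). Their calls were also lost with the replicate number as a block (edgeR adjusted p = 0.0766). The number called was 2183 without brother pool 1, 639 without brother pool 2, 54 without isolated pool 2, 35 without unrelated pool 1 and 15 without unrelated pool 2. It was 2 without isolated pool 3 and 1 without isolated pool 1, brother pool 3 or unrelated pool 3. DESeq2 gave 745 higher and 710 lower.

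The effects of the 2 kinds of male were also set against each other across loci, which are not independent replicates. Log2 fold changes against isolation had a Pearson r of 0.627 and the same sign at 78.5% of 15486 loci. Because both effects share the isolated pools, simulated data with no effect gave a mean r of 0.501 (highest of 100, 0.532) and the same sign at 66.7%. The covariance was 0.149, against a simulated mean of 0.0757 and a highest of 0.0828. Without brother pool 1, r was 0.489 against a simulated mean of 0.445, and the covariance was 0.122 against 0.0403. In that fit 224 loci were called higher and 259 lower in both comparisons, and 3 were called in opposite directions. Independent lists of those sizes would share 31.8 and 32.5, values that leave out the shared controls, so the counts do not measure a shared effect. The effects were also taken with no isolated pool shared, with 1 isolated pool for one effect and the other 2 for the other, in all 6 ways. The mean r was then 0.377 (0.285 to 0.44) and the mean covariance 0.109, against simulated means of 0.000245 and 5.95e-05. Without brother pool 1 the mean r was 0.271 (0.152 to 0.379) and the mean covariance 0.0802. The 6 ways reuse the same pools, so their ranges are not independent errors. The simulated loci varied independently of each other and had the same spread in every pool. Real loci are not independent, and the real pools differed in spread, with brother pool 1 standing apart. The gap to the simulated values therefore does not measure a shared effect.

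The joint test for any difference among the 3 groups called 41 loci with all 9 pools (edgeR, adjusted p under 0.05). It called 2446 without brother pool 1, 78 without unrelated pool 1, 10 without unrelated pool 2 and 1 without any one of the other 6 pools.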

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

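The alternatives were fixed before the data were examined, except unscaled library sizes, quality weights and the fits without brother pool 1 and unrelated pool 1 together or, for the correlation, without brother pool 1 or with no isolated pool shared. Counts are given in the order brother against isolated, unrelated against isolated, brother against unrelated, both courted groups against isolated, and any difference, for which the main values were 337, 0, 30, 170 and 41. DESeq2 called 1739, 424, 191, 1455 and 1292. Treating the 18 libraries as independent called 3942, 1508, 415, 3430 and 3403, which counts technical replicates as biological ones. With duplicateCorrelation, 1323, 390, 1332 and 988 were called for all but brother against unrelated, where the 41 calls included only 11 of the 30. Sample quality weights, which gave brother pool 1 a weight of 0.108, called 3712, 2316, 752, 3842 and 4056. Without both first courted pools, 2520, 279, 550, 1960 and 2024 were called. Fitting only the groups compared gave 61, 1047 and 1 for the 3 pairs. A minimum change of 2-fold left 110 for brother against isolated and 43 for courted against isolated. The first technical replicate alone called 15 for brother against unrelated and 19 for any difference, and the second alone 198 for brother against isolated. The filter of 1 CPM in 3 pools gave 321 for courted against isolated, and unscaled library sizes 73 for any difference. Leaving out single pools gave ranges of 3 to 2494, 0 to 807, 1 to 720, 1 to 2183 and 1 to 2446, with every maximum reached without brother pool 1. RLE and upper-quartile scaling, no filter and a robust fit kept every count within 1.5 times. With the replicate number as a block (replicate block), 39, 0, 3, 1 and 1 were called. Deviations of same-numbered pools from their group means correlated between -0.308 and 0.186, and no pool correlated best with its own number in both other groups (brother pools 1 and 3 did among the unrelated pools, and unrelated pool 1 among the brother pools), so the numbers were not taken to pair the pools. The r of the 2 courtship effects was 0.714 for loci above the median expression, 0.489 without brother pool 1, 0.377 with no isolated pool shared, 0.271 with both of these, and 0.469 when the effects came from different technical replicates, in both directions. For loci above the median expression, simulated data with no effect gave a mean r of 0.496. The 0.469 still rests on the same isolated pools for both effects, and no simulated value was made for it. Each of the 11 named results kept its direction in all alternatives run, 271 in all. The naming rule required pools that did not overlap between the groups compared, so a change of direction was unlikely from the start. Calls were lost in 41 of the 271, among them 7 without brother pool 3, 6 without isolated pool 1 and 6 without isolated pool 3. Unrelated pool 3 left out, the block and the 2-fold minimum each lost 5. Apart from the tests of the fixed gene lists, which need gene names, the alternatives fixed beforehand were run. For the calls lost with a 2-fold minimum the setting itself is the reason. Losses with a pool left out depended on which pool it was, and no named call was lost without brother pool 1 or unrelated pool 1. For these and the other settings the cause was not tested.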

Other observations

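The loci that set brother pool 1 apart were described by their level in the other pools. The 1118 loci over 2-fold above all other pools lay at a median of 4.54 times the mean of the other 8 pools and held 1.26% of that pool's counts. In unrelated pool 1 the same loci had a median log2 ratio of 0.38 to the other pools except brother pool 1, and in isolated pool 1 and brother pool 2 that median was -0.35 and -0.48. The tests of composition, neighbouring loci, courtship by a brother, material of another tissue or organism and the shared spread were chosen after the results were seen, and so was the minimum of 0.5 CPM below. The tests of an outside source, a sequencing run and an even background had cut-offs set before those tests were run. They name unrelated pool 1 or brother pool 1, so the patterns had already been seen. Exact intervals on shares of loci below count loci as independent. Loci of the same pools are not independent, so these intervals are too narrow.

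The first pattern is the set of 29 loci lower in brother than in unrelated pools, 28 of them by over 8-fold. One stretch of neighbouring loci is argued against, as far as locus numbers follow position, since the fullest window of 200 consecutive numbers held 3 of the 29 (mean r of adjacent loci 0.0452, against 0.00267 for random pairs). One outside source whose amount differs between pools, such as a tissue, a microbe or a family genotype, stays open. Loci were picked in the isolated and unrelated pools, as those in unrelated pool 1 under 0.5 times the lowest of the other 5. Of these 237 loci, 38% (exact 95% interval 31.8% to 44.5%) were under 0.25 times the isolated level in the brother pools. That is above the 0.612% of matched loci but below the 50% set before the test was run. With a minimum of 0.5 CPM, not part of that test as set, it was 55.2% (64 of 116, interval 45.7% to 64.4%). Unrelated pool 1 was low for the 29 loci, which were chosen as low in the brother pools, and 21 of the 116 belong to the 29. The pick is thus not independent of the brother pools, and these shares are no independent support for one source. A fixed composition of that source was left undecided, since the SD of the log2 ratio of unrelated pool 1 to unrelated pools 2 and 3 across the set, 0.502, lay between the 5th (0.296) and 95th (0.764) percentiles of matched sets, whose median was 0.441. Courtship by a brother cannot be told apart from a difference between the females used, because unrelated pool 1 lay between the groups, at a median of 31.9% of the isolated level against at most 1.29% in a brother pool, and for XLOC_010657 a fall within 10 min would need a half-life of at most 0.96 min with no new transcription.

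The second pattern is the distance of brother pool 1 from the rest. A fault of one sequencing run is argued against, because 63.3% of the loci over 2-fold above all other pools in either technical replicate were so in both (exact 95% interval 60.5% to 66%; 774 shared, of 1013 and 984). An even background such as genomic DNA was tested at the lowest 10% of loci by expression. Of these, 42% lay at least 2-fold above the mean of the other 8 pools (exact 95% interval 39.5% to 44.5%), under the 50% set before the test was run. A background below the median level of these loci, 0.188 CPM, could also give under 50%, so this share does not decide. The next 10% of loci had a median ratio of 0.967, which argues against an even background as the whole cause. A part of such a background, or an uneven one, stays open, since the lowest 10% had a median ratio of 1.48. The share of loci above fell through 20.7%, 20.1%, 19.2% and 15.8% to 8.46% over the next 5 steps of 10%. Brother pools 2 and 3 and unrelated pool 1 had 8.91%, 5.75% and 4.07% of the lowest 10% above. These pools were set against means that include brother pool 1, in steps ranked without it. Their shares are therefore not like for like with the 42% of brother pool 1. Material of another tissue or organism cannot be told apart from a difference between females, since loci carry no gene names: the 10 loci with the largest excess held 22.4% of it, which decides neither way.

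The third pattern is the 0 calls of edgeR for unrelated against isolated in the fit of all 9 pools, with 1678 loci at an unadjusted p under 0.05 and 424 called by DESeq2. The 1047 calls of the 6 pools fitted alone are consistent with the spread of brother pool 1, which enters the shared estimate, as a candidate cause. A biological reason was not tested.

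Other splits of the same pools were fitted for each count. For brother against isolated the real split called 337 loci and the highest of the 9 other splits 0, and for brother against unrelated 30 and 0. For unrelated against isolated the fit of all 9 pools called 0 in all 10 splits, and the fit of the 6 pools alone called 1047 for the real split and 0 for the highest other. These 10 splits are too few for a share under 0.05. For both courted groups against isolation, 1 of 84 choices of 3 control pools (the real one) gave as many as 170 calls, with 63 the highest other, and for any difference among the groups 1 of 100 splits gave as many as 41, with 21 the highest other. For these last 2 counts the share of splits with as many calls was under 0.05. The other splits mix pools of different groups, and for the courted groups the 6 remaining pools took their labels at random. The shares therefore argue only against all pools being interchangeable. They do not test courtship as the reason.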
